A study of Danio rerio with 14 samples.

How the data were processed

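The series holds RNA-seq gene counts of 14 samples of zebrafish embryos taken at 72 hpf, 3 or 4 per group, in 4 groups of genotype (wild type or ahrra-null) and exposure (DMSO or TCDD). Groups and replicate numbers were taken from the sample titles. Total RNA was extracted with a BioRad Aurum kit and made into unstranded libraries with an Illumina TruSeq kit, per the labels' protocols. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart. The values used are whole-number read counts per Ensembl gene ID, as the authors deposited them, not normalized. Per the submitters' processing notes the tools were cutadapt, TopHat2, SAMtools, HTSeq and edgeR and the genome build was GRCz10. Their versions, the annotation release, the counting settings and the treatment of reads with several matches are not given in the sources used here. Zebrafish has many paralogs, and reads of close copies may have been lost or split between them.

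Each file listed the same 32105 genes. No genome or annotation of the build used was at hand, so no coordinates are given. Symbols were taken from a table of gene IDs and symbols, which matched 26269 of the IDs, and 4144 of these share a symbol with another ID. Such genes are printed with their ID. Symbols in capitals are those the table gives for some zebrafish genes.

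Genes were kept for testing with edgeR's filterByExpr by group at its minimum count of 10, which left 21606 genes with 99.9% of all counts and set aside 10499. Library sizes were scaled by TMM. A negative binomial quasi-likelihood model with robust estimation was fitted over all 14 libraries and 4 groups, so that the groups share an estimate of the spread, and 5 contrasts were tested in it: the TCDD effect in wild type and in ahrra-null, the genotype effect (ahrra-null minus wild type) in DMSO and in TCDD, and the interaction of genotype and TCDD. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no threshold on the fold. Log2 fold changes use edgeR's prior count of 0.125. CPM were computed with TMM-scaled library sizes. The common biological coefficient of variation was 7.19%. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

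The named genes were chosen by a rule. For each contrast they are, among called genes with an average log2 CPM of at least 1, a symbol that is no clone or locus name and no overlap of CPM between the groups (a condition dropped for the interaction), the 10 with the largest positive and the 10 with the largest negative log2 fold change. In addition they are every AHR target gene in every contrast, the 4 called members with the smallest adjusted p of every other called list, and ahrra and ahrrb. The text gives those that kept their call in most alternatives with their values, and counts of the rest. With 3 libraries against 3 a random gene has no overlap between groups in 10% of cases.

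There were 26 gene lists, written from general knowledge: AHR target genes, AHR pathway components, Nrf2 and oxidative stress response, cartilage and jaw, bone and dermal matrix, heart muscle, fast skeletal muscle, photoreceptor and phototransduction, lens crystallin, erythroid and globin, neutrophil and macrophage, interferon and acute phase response, liver, exocrine pancreas, intestine, synaptic and neuronal, glia and myelin, epidermis and keratinocyte, vascular endothelium, circadian clock, cell cycle, p53 and apoptosis, heat shock and unfolded protein response, sterol and steroid synthesis, vitellogenin and yolk, and germ and maternal stock. Of their 587 symbols 553 were found, as 601 gene IDs. Where a symbol was missing, all genes bearing it without its paralog letter or number were taken, or else a synonym. Some list members may therefore be paralogs of the gene meant. The AHR target and Nrf2 lists share nqo1, gstp1 and gstp2, so their results are not independent. A list was tested with limma's camera on voom log2 CPM, two-sided, with a preset correlation of 0.01, where at least 5 members were tested for expression; this left out vitellogenin and yolk, of which no result is given. Camera p-values were adjusted over the lists of a contrast. For each list the members called over all genes and those called when adjusted over the list alone were counted.

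The groups, the tests, the rule for named genes, the gene lists and the alternatives were fixed before the data were examined. The alternatives were median-ratio and upper-quartile scaling, DESeq2, limma voom with sample quality weights, no filter beyond 1 read in total, a filter of 1 CPM in 3 libraries, a fit of only the libraries of the contrast, a threshold of 2-fold, 1 surrogate variable from svaseq, and leaving out each library in turn. For lists, camera with an estimated correlation and the directional test fry were also run. Fry asks whether the genes of a list move, on balance, in a direction, and does not compare them with other genes. Leaving out genes on the chromosome of ahrra was also planned and was not run, because only 69.5% of the tested genes could be placed on a chromosome by symbol, under the 80% set for such a check.

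The procedure was tested on counts simulated from the means and library sizes of the real samples with 200 genes changed. The changed genes were drawn only from those with a mean of at least 1 CPM. The shares called below therefore do not hold for genes of lower expression. A further set of genes was shifted 1.5-fold as a list and is not counted as a false call. In the TCDD effect in wild type, over 21424 simulated genes tested, 73.1%, 91.0% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 17 false calls (8.29% of calls). In the TCDD effect in ahrra-null the shares were 79.1%, 95.5% and 100% with the TCDD group changed (21423 genes; 11 false calls, 5.14%) and 65.7%, 97.0% and 100% with the DMSO group changed (21415 genes; 16 false calls, 7.84%). In the genotype effect in DMSO, over 21415 genes, they were 68.7%, 94.0% and 100% (10 false calls, 5.08%). In the genotype effect in TCDD they were 79.1%, 89.6% and 100% with the ahrra-null group changed (12 false calls, 5.71%) and 76.1%, 95.5% and 98.5% with the wild-type group changed (10 false calls, 4.88%). In the interaction, over the 3 simulations, they were 43.3% to 61.2%, 80.6% to 88.1% and 93.9% to 97.0%. A shifted list was called in each of 9 tests, and 0 of 24 unchanged lists in each. The simulated genes varied independently, and the unchanged lists were drawn at random. Members of real lists were correlated, with an estimate of 0.593 for exocrine pancreas in the TCDD effect in wild type. The simulation therefore says nothing on false calls of such lists with the preset correlation. For the TCDD effect in wild type, voom called 178 and DESeq2 177 of the 200.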

Results

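Transcripts of zebrafish embryos were counted by RNA-seq in 14 libraries at 72 h post-fertilization (hpf). The embryos were wild type or ahrra-null, a line made with zinc finger nucleases, and the labels give Tupfel longfin as the strain of all of them. ahrra encodes a repressor of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. TCDD is a dioxin and a potent AHR ligand. The series asks how embryos without a working ahrra differ in basal and in TCDD-induced expression. Embryos received 0.01% DMSO as carrier or 2 nM TCDD at 6 hpf, in an exposure of 1 h, and were then rinsed and raised without it until sampling. The groups held 3 libraries of wild-type DMSO, 3 of wild-type TCDD, 4 of ahrra-null DMSO and 4 of ahrra-null TCDD. The clutch and the number of embryos behind each library are not stated, so p-values measure only the spread between these samples, which may be technical. Unless another n is given, values below are mean CPM ± SD over the 3 or 4 libraries of a group. Log2 fold changes are given ± SE, with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test. The fit itself gives no SE. The SE printed is the size of the log2 fold change divided by the square root of the test's F statistic. It is an approximation, and the SEs of different contrasts of a gene need not match each other.

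Total counts ran from 16.9 to 23.1 M (mega) reads per library. The wild-type DMSO libraries (replicates 2, 3 and 4) held 19.3, 19.4 and 18.3 M counts, and the wild-type TCDD libraries (replicates 6, 7 and 8) 23.1, 18.0 and 18.3 M. The ahrra-null DMSO libraries (replicates 9 to 12) held 21.0, 18.9, 18.7 and 22.7 M, and the ahrra-null TCDD libraries (replicates 13 to 16) 18.0, 18.1, 16.9 and 16.9 M. Of 32105 genes listed, 21606 passed the filter on low counts. Replicates of a group differed by more than counting noise in all 18 pairs (chi-square per degree of freedom 2.52 to 18.4), so no pair looked like repeat files of the same library. The first principal component, with 42.1% of the variance, parted the genotypes, and the second held 11.8%.

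**Figure D1:**
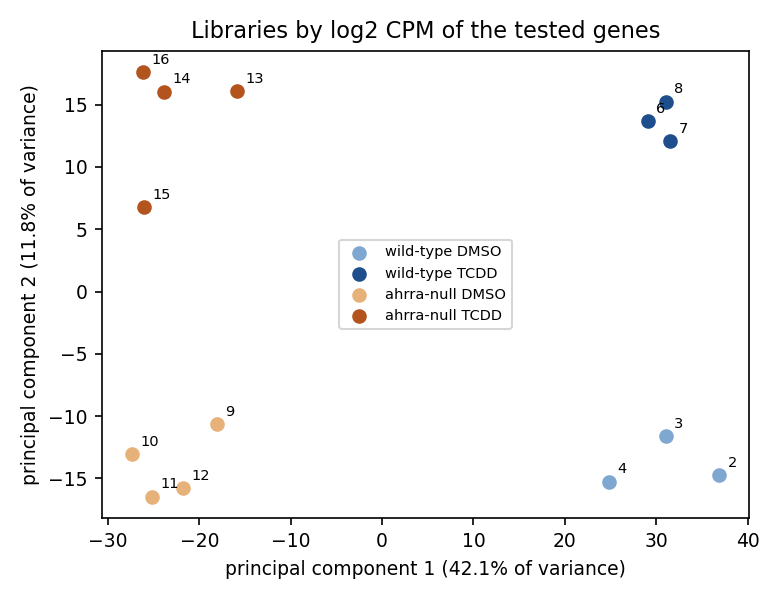
First and second principal components of log2 CPM, with each axis labelled by its share of the variance (42.1% and 11.8%). Each point is a library, coloured by its group and numbered by its replicate, and the first component parts the 6 wild-type from the 8 ahrra-null libraries.

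The targeted gene, ahrra (ENSDARG00000099702), stood near the detection floor with carrier in both lines and rose with TCDD in both. It measured 1.39, 0.612 and 0.810 CPM in the wild-type DMSO libraries and 1.09, 1.42, 0.879 and 1.19 CPM in the ahrra-null DMSO libraries. With TCDD it measured 20.5, 14.1 and 17.8 CPM in wild type and 44.8, 54.5, 21.1 and 52.1 CPM in ahrra-null. The log2 difference between ahrra-null and wild type was 0.30 ± 0.75, adjusted p = 0.824 with carrier and 1.3 ± 0.28, adjusted p = 0.00714 with TCDD. The call with TCDD was lost when only the libraries of the 2 compared groups entered the fit (adjusted p = 0.0565). The transcript of the targeted gene was thus not lower in any ahrra-null group. The position of the lesion is not given in the sources used here, and a nuclease lesion need not lower the transcript, so these levels do not check the genotype labels.

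**Figure D2:**
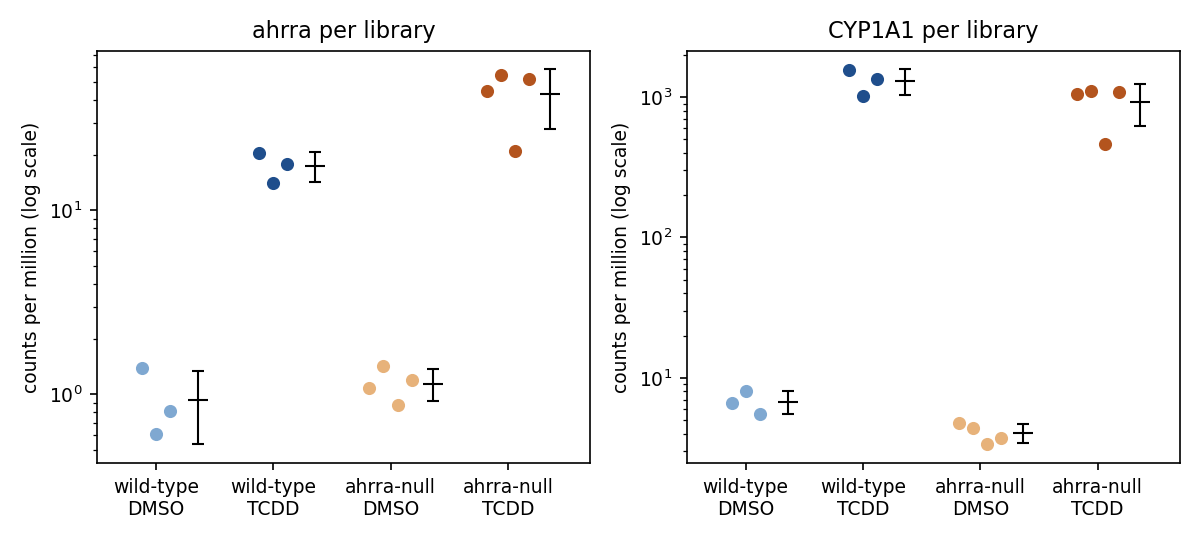
CPM of ahrra and CYP1A1 in each library on a log axis, by group, with a point for each library and a black bar for the mean ± SD of the group. With TCDD, ahrra lies between 14.1 and 20.5 CPM in wild type and between 21.1 and 54.5 CPM in ahrra-null.

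TCDD in wild-type embryos raised the enzymes and feedback genes of AHR signalling and lowered other genes, heart muscle transcripts among them. CYP1A1 (ENSDARG00000098315), a monooxygenase whose induction is the usual readout of AHR activation, stood at 1300.2 ± 273 against 6.74 ± 1.25 CPM (log2 fold change 7.59 ± 0.41, adjusted p = 7.76e-06). cyp1c1 (ENSDARG00000101195), of the same enzyme family, stood at 313 ± 9.80 against 13.9 ± 1.91 CPM (4.50 ± 0.25, adjusted p = 7.76e-06), and cyp1c2 (ENSDARG00000101789) at 66.8 ± 7.35 against 3.62 ± 0.53 CPM (4.21 ± 0.34, adjusted p = 0.000168). CYP1B1 (ENSDARG00000068934) rose by 2.60 ± 0.30 on the log2 scale (adjusted p = 0.0019). ahrra rose by 4.23 ± 0.50 (adjusted p = 0.00234) and its paralog ahrrb (ENSDARG00000052618) by 2.67 ± 0.34 (adjusted p = 0.000298). The growth factor gene fgf7 (ENSDARG00000059387) rose from 3.06 ± 0.728 to 36.2 ± 3.81 CPM (3.56 ± 0.32, adjusted p = 0.000266). Of the 21 genes tested on the list of AHR targets, 11 rose and 0 fell, and 14 rose adjusted over the list alone (camera adjusted p = 1.59e-29; adjusted p = 0.0333 with an estimated correlation). Its other calls included sult6b1 (ENSDARG00000086826), a sulfotransferase, at 1.44 ± 0.18, adjusted p = 0.00291, and tiparp (ENSDARG00000061841), a mono-ADP-ribosyltransferase, at 0.63 ± 0.11, adjusted p = 0.00764. NQO1 (ENSDARG00000010250), a quinone reductase on the list, did not pass (0.16 ± 0.09, adjusted p = 0.679). Outside the list, ugt1b5 (ENSDARG00000089507), a glucuronosyltransferase, stood at 52.8 ± 1.23 against 13.7 ± 0.696 CPM (1.94 ± 0.12, adjusted p = 4.37e-08). The cathepsin gene ctsl.1 (ENSDARG00000003902) rose by 2.41 ± 0.27 (adjusted p = 0.000374) and mamdc2b (ENSDARG00000073695) by 2.33 ± 0.27 (adjusted p = 0.000272). ahr2 (ENSDARG00000021833), the receptor through which TCDD acts in zebrafish embryos, rose by 0.82 (adjusted p = 1.66e-07); it lies outside the naming rule for this comparison and was chosen after its values were seen. The list of AHR pathway components, which shares ahrra and ahrrb with the targets, was not called (adjusted p = 0.16).

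Among the falls in wild type, the heart muscle list went down as a group: 5 of 14 members fell and 0 rose, with 9 falls adjusted over the list alone (median log2 fold change -0.53, camera adjusted p = 3.38e-12; adjusted p = 0.0333 with an estimated correlation). nppa (ENSDARG00000052960), atrial natriuretic peptide, fell from 2.90 ± 0.171 to 1.2 ± 0.365 CPM (-1.29 ± 0.22, adjusted p = 0.00202), and MYH6 (ENSDARG00000079564), a cardiac myosin heavy chain, from 80.7 ± 10.4 to 55.6 ± 5.65 CPM (-0.54 ± 0.09, adjusted p = 0.0058). Another gene of the list, printed as myh6 (ENSDARG00000090637), had at most 9 counts in a library and was not tested. Which cardiac myosin the symbol MYH6 stands for was not settled. SOX9 (ENSDARG00000043923), a transcription factor of the chondrocyte lineage, fell by 0.83 on the log2 scale (SE 0.09, adjusted p = 4.03e-06). The cartilage list had 1 rise and 1 fall among 23 members, with 2 and 5 adjusted over the list alone (median -0.13, camera adjusted p = 4.65e-05; adjusted p = 0.373 with an estimated correlation). Among the 10 largest falls by the naming rule were FHL5 (ENSDARG00000014805), a LIM-domain protein, at -2.26 ± 0.32, adjusted p = 0.00169, and the chemokine gene ccl34b.1 (ENSDARG00000093608) at -1.37 ± 0.24, adjusted p = 0.0027. The keratin gene krt94 (ENSDARG00000044975) fell from 43.4 ± 6.72 to 24.9 ± 2.54 CPM (-0.81 ± 0.11, adjusted p = 0.00109). It was the only called member among 21 on the epidermis list (3 fell adjusted over the list alone; camera adjusted p = 0.0372, and 0.591 with an estimated correlation). That list's call was lost without wild-type DMSO replicate 2 (adjusted p = 0.35), wild-type DMSO replicate 3 (0.227), wild-type TCDD replicate 6 (0.0623) or wild-type TCDD replicate 8 (0.118).

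Transcripts of digestive organs and of photoreceptors were lower on average with TCDD in wild type, with few single genes called. On the exocrine pancreas list the median log2 fold change was -1.52; 3 of 12 members fell, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.52e-11; adjusted p = 0.148 with an estimated correlation). CPB1 (ENSDARG00000045442), a carboxypeptidase zymogen, fell from 7.76 ± 2.34 to 3.61 ± 0.299 CPM (-1.1 ± 0.17, adjusted p = 0.000852). On the liver list 1 of 32 members fell and 12 fell adjusted over the list alone (median -0.44, camera adjusted p = 1.74e-17; adjusted p = 0.193 with an estimated correlation). No member was called on the intestine list (median -0.39, 0.0039; adjusted p = 0.487 with an estimated correlation) or on the photoreceptor list (median -0.32, 1.8e-09; adjusted p = 0.373 with an estimated correlation), where 3 fell adjusted over the list alone. The intestine call was lost without wild-type DMSO replicate 2 (adjusted p = 0.96, median 0.05). Without the same library the medians were -0.26 for liver and -0.13 for photoreceptors, and the latter was -0.56 without wild-type DMSO replicate 4. These lists were spread widely among the wild-type DMSO libraries. The mean log2 CPM of the pancreas list was 2.52, 1.76 and 0.80 in replicates 2, 3 and 4, against 0.22 to 0.49 with TCDD. That of the photoreceptor list was 5.66, 5.27 and 4.71, against 4.78 to 5.05. The liver list ran from 4.01 in replicate 2 to 3.24 in replicate 4, and the intestine list from 3.27 to 2.30.

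In all, TCDD changed 185 genes in wild type, 104 higher and 81 lower, of which 53 changed at least 2-fold. There were 3 further lists called with no member called: Nrf2 and oxidative stress response (median 0.07, 4 rising adjusted over the list alone, camera adjusted p = 0.000199; adjusted p = 0.373 with an estimated correlation), fast skeletal muscle (median -0.11, 2.62e-05; adjusted p = 0.451 with an estimated correlation), and germ and maternal stock (median -0.57, 2 falling adjusted over the list alone, 0.00626; adjusted p = 0.0965 with an estimated correlation). The Nrf2 median was 0.11 without wild-type DMSO replicate 2, and the fast muscle median -0.17 without wild-type DMSO replicate 4. The lists of bone (0.106), lens (0.291), erythroid (0.726), neutrophil and macrophage (0.124), interferon (0.997), neuronal (0.291), glial (0.633) and vascular genes (0.129) were not called, with camera adjusted p in brackets. Neither were those of the circadian clock (0.0891), cell cycle (0.291), p53 response (0.379), heat shock (0.129) and sterol synthesis (0.0711). The count of called genes was 82 without wild-type TCDD replicate 6, 89 without wild-type DMSO replicate 3, 94 without wild-type TCDD replicate 8 and 388, with 118 higher and 270 lower, without wild-type DMSO replicate 4. It was 381, with 159 higher and 222 lower, with limma voom and sample quality weights, and 381 with 1 surrogate variable.

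In ahrra-null embryos TCDD raised the same family of enzymes and feedback genes. The cell cycle and lens lists were called down with the preset correlation and not with an estimated one (adjusted p = 0.128 and 0.129). CYP1A1 stood at 930.0 ± 310.3 against 4.06 ± 0.634 CPM (7.83 ± 0.37, adjusted p = 1.87e-06), cyp1c1 at 358 ± 95.8 against 10.8 ± 0.822 CPM (5.05 ± 0.22, adjusted p = 1.34e-06) and cyp1c2 at 76.2 ± 24.4 against 2.82 ± 0.335 CPM (4.75 ± 0.30, adjusted p = 1.89e-05). ahrra rose from 1.14 ± 0.225 to 43.1 ± 15.2 CPM (5.23 ± 0.38, adjusted p = 5.43e-05) and ahrrb from 0.661 ± 0.396 to 2.73 ± 0.89 CPM (2.08 ± 0.33, adjusted p = 0.00256). fgf7 rose by 3.62 ± 0.28 (adjusted p = 6.08e-05), CYP1B1 by 2.63 ± 0.27 (adjusted p = 0.000657), sult6b1 by 1.68 ± 0.16 (adjusted p = 0.000305) and the forkhead gene FOXQ1 (ENSDARG00000030896) by 1.70 ± 0.23 (adjusted p = 0.00374). Of the 21 AHR targets tested, 11 rose and 0 fell, and 17 rose adjusted over the list alone (camera adjusted p = 1.7e-35; adjusted p = 0.0197 with an estimated correlation). Beside this group, replicate 15 stood below the other ahrra-null TCDD libraries: CYP1A1 was 465 CPM there and 1057 to 1103 CPM in the others, and cyp1c1 was 216 CPM against 387 to 421 CPM. Outside the list, ugt1b5 rose by 2.21 ± 0.10 (adjusted p = 3.21e-10), ctsl.1 from 1.2 ± 0.409 to 14.2 ± 3.51 CPM (3.57 ± 0.26, adjusted p = 4.37e-06) and ifitm1 (ENSDARG00000093303), an interferon-induced membrane protein, by 2.35 ± 0.34 (adjusted p = 0.00208). The receptor gene ahr2 rose from 64.0 ± 3.29 to 127 ± 11 CPM (0.99 ± 0.06, adjusted p = 3.21e-10). With ahrra and ahrrb it made up the 3 rises among 18 AHR pathway components, 3 adjusted over the list alone (camera adjusted p = 0.0164; adjusted p = 0.129 with an estimated correlation, and 0.0529 without ahrra-null DMSO replicate 9).

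Single antioxidant, cartilage and heart genes were called with TCDD in ahrra-null, and most members of these lists were not. nfe2l2b (ENSDARG00000089697), of the Nrf2 family of stress-response transcription factors, rose from 2.71 ± 0.344 to 4.89 ± 0.715 CPM (0.85 ± 0.14, adjusted p = 0.00167) and was among 3 rises and 0 falls of 22 on the Nrf2 list. gstp1.2 (ENSDARG00000104068), which is also on the AHR target list, was another of these rises (0.42 on the log2 scale). Adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.000745; adjusted p = 0.431 with an estimated correlation). SOX9 (ENSDARG00000043923) fell from 44.9 ± 4.07 to 26.0 ± 3.17 CPM (-0.79 ± 0.08, adjusted p = 1.32e-06), while the cartilage matrix genes MATN4 (ENSDARG00000015947) and ucmaa (ENSDARG00000027799) rose by 0.49 ± 0.06 (adjusted p = 1.73e-05) and 1.09 ± 0.22 (adjusted p = 0.00807). The 23 cartilage genes had a median of -0.12, with 2 rising and 7 falling adjusted over the list alone (camera adjusted p = 0.000174; adjusted p = 0.431 with an estimated correlation). nppa fell by 0.97 on the log2 scale (SE 0.18, adjusted p = 0.00546) and was the only called member of the heart list, 1 of 14 adjusted over the list alone (median -0.16, camera adjusted p = 0.00981; adjusted p = 0.431 with an estimated correlation). The heart call was lost without ahrra-null TCDD replicate 15 (adjusted p = 0.0621) or 16 (0.0987), and its median was -0.10 without ahrra-null DMSO replicate 9 and -0.07 without TCDD replicate 16. Other falls were ccl34b.1 at -1.73 ± 0.22, adjusted p = 6.08e-05, APLNR (ENSDARG00000004447), the apelin receptor, at -0.84 ± 0.16, adjusted p = 0.00584, the chemokine gene cxcl12b (ENSDARG00000055100) at -0.84 ± 0.11, adjusted p = 0.000624, and LRAT (ENSDARG00000037278), a retinol acyltransferase, at -0.83 ± 0.10, adjusted p = 3.89e-05.

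Cell cycle genes were lower with TCDD in ahrra-null: all 26 tested had a negative log2 fold change (median -0.25), 3 fell and 20 fell adjusted over the list alone (camera adjusted p = 2.62e-20; adjusted p = 0.128 with an estimated correlation). The 3 calls, plk1 (ENSDARG00000058471) at -0.27, MCM5 (ENSDARG00000019507) at -0.26 and RRM1 (ENSDARG00000014017) at -0.28, all ended without ahrra-null DMSO replicate 11 or 12 or ahrra-null TCDD replicate 13, 14 or 16, and over all alternatives adjusted p reached 0.129, 0.174 and 0.175. Lens genes had a median of -0.22, with 2 of 22 falling and 15 falling adjusted over the list alone (camera adjusted p = 8.79e-14; adjusted p = 0.129 with an estimated correlation). Without ahrra-null DMSO replicate 12, in which the list stood highest, the median was -0.14. The lens aquaporin gene MIP (ENSDARG00000013963) fell by 0.31 (SE 0.06, adjusted p = 0.00551); another gene of that symbol is also listed, and reads may be shared between them. alas2 (ENSDARG00000038643), which encodes the first enzyme of erythroid heme synthesis, fell by 0.35 (SE 0.07, adjusted p = 0.00617). The erythroid list had 1 fall among 16, with 1 rise and 4 falls adjusted over the list alone (camera adjusted p = 0.00493; adjusted p = 0.339 with an estimated correlation). The liver list had 1 fall among 32 and 2 adjusted over the list alone (median -0.24, 9.5e-07; adjusted p = 0.463 with an estimated correlation). Its median was -0.36 without ahrra-null TCDD replicate 13 and -0.12 without replicate 16. The neuronal and clock lists were called up with small medians of 0.04 and 0.08 and no called member (camera adjusted p = 0.0132 and 0.013; adjusted p = 0.535 for each with an estimated correlation). The neuronal call was lost without ahrra-null DMSO replicate 12 (adjusted p = 0.432) or TCDD replicate 16 (0.0987), and the clock call without ahrra-null DMSO replicate 12 (0.232) or TCDD replicate 13 (0.135). The neuronal median was 0.07, 0.06 and 0.01 without ahrra-null DMSO replicates 9, 10 and 12, and the clock median 0.04 without replicate 12. The other 14 lists were not called. In all, 254 genes changed, 176 higher and 78 lower, and 44 changed at least 2-fold. The count was 141 without ahrra-null TCDD replicate 13, 148 without TCDD replicate 14, 149 without TCDD replicate 16, 158 without DMSO replicate 11 and 167 without DMSO replicate 12, and 394 with 1 surrogate variable.

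The TCDD responses of the lines, which share no library, overlapped far more than independent lists would. Called in both were 93 genes, of which 70 rose in both, 23 fell in both and 0 moved in opposite directions. Independent lists of these sizes would share 0.847 rises and 0.292 falls. The comparisons came from the same fit, with a shared estimate of each gene's spread, so the lists are not fully independent. These chance numbers are therefore a rough guide and may be too low. CYP1A1, cyp1c1, cyp1c2, ahrra, ahrrb, fgf7, ugt1b5, ctsl.1 and ahr2 were among the shared rises, and nppa, ccl34b.1, LRAT, cxcl12b and SOX9 (ENSDARG00000043923) among the shared falls. Across the 346 genes called in either line, the log2 fold changes correlated with Pearson r 0.888 and Spearman rho 0.836, and 320 (92.5%) had the same sign. The 346 genes were picked for passing in at least 1 line, and over all tested genes Pearson r was 0.408. These are correlations across genes, which are not independent replicates. The shared count was 58 without wild-type TCDD replicate 6, 58 without wild-type TCDD replicate 8 and 59 without wild-type DMSO replicate 3, 166 with 1 surrogate variable, and 25 when a 2-fold change was asked for in both.

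**Figure D3:**
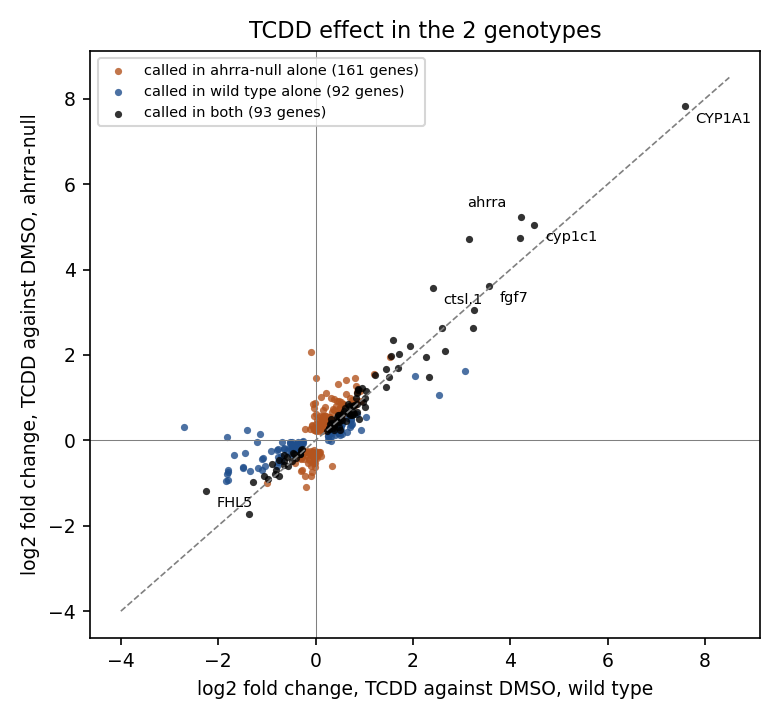
Log2 fold change with TCDD in wild type (x axis) and in ahrra-null (y axis), a point for each of the 346 genes called in either line, coloured by where it was called. Genes called in neither line are not drawn. The 93 genes called in both lines lie in the lower left and upper right, and none of them has opposite signs.

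With carrier, the lines differed in 4670 genes (21.6% of those tested), 2141 higher and 2529 lower in ahrra-null. With the preset correlation the lens list was called higher and the liver, intestine, pancreas and photoreceptor lists lower in ahrra-null, and none of the 25 lists was called with an estimated correlation. FBN2 (ENSDARG00000051896), a fibrillin of extracellular microfibrils, stood at 10 ± 1.62 against 0.847 ± 0.605 CPM (3.55 ± 0.31, adjusted p = 1.46e-06), and RXFP2 (ENSDARG00000032820), a relaxin-family receptor, at 12 ± 2.76 against 2.1 ± 0.827 CPM (2.51 ± 0.21, adjusted p = 3.64e-07). ms4a17a.9 (ENSDARG00000094854) stood at 1.09 ± 0.431 against 10.6 ± 1.48 CPM (-3.25 ± 0.26, adjusted p = 3.7e-07), PIPOX (ENSDARG00000055591), a peroxisomal oxidase, at 1.06 ± 0.207 against 5.95 ± 0.711 CPM (-2.47 ± 0.16, adjusted p = 3.99e-10), and ptgdsb.1 (ENSDARG00000027088), a prostaglandin D synthase, at 14 ± 1.4 against 81.6 ± 24.9 CPM (-2.54 ± 0.19, adjusted p = 6.02e-06). Also among the largest differences, fbxo44.9 (ENSDARG00000071029) and fbxo44.10 (ENSDARG00000092077) were higher by 2.57 ± 0.23 and 2.29 ± 0.23 on the log2 scale, the kinase gene PRKCH (ENSDARG00000018382) by 2.15 ± 0.22 and slx4ip (ENSDARG00000039069) by 1.85 ± 0.19 (largest adjusted p of these 1.44e-06). Lower by the same rule were the myosin gene myhc4 (ENSDARG00000035438) at -2.23 ± 0.36, adjusted p = 0.00171, plekhf1 (ENSDARG00000102435) at -2.19 ± 0.14, adjusted p = 2.92e-10, and the hatching enzyme gene he1.1 (ENSDARG00000023656) at -2.06 ± 0.26, adjusted p = 0.000139. The fbxo44, ms4a17a, myosin and he1 genes have close paralogs between which the counting could split reads.

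In the eye lists the genotypes differed in opposite directions with carrier. Of 22 lens genes, 15 were higher in ahrra-null and 0 lower, and 16 were higher adjusted over the list alone (median 0.46, camera adjusted p = 6.02e-11; adjusted p = 0.519 with an estimated correlation). CRYAA (ENSDARG00000053502), the alpha A crystallin, stood at 52.8 ± 6.62 against 30.1 ± 4.41 CPM (0.81 ± 0.10, adjusted p = 9.31e-06) and LIM2 (ENSDARG00000041295), a lens membrane protein, at 22.7 ± 2.11 against 12.7 ± 0.912 CPM (0.83 ± 0.09, adjusted p = 4.31e-07). Of 39 photoreceptor genes, 2 were higher and 9 lower, or 2 and 23 adjusted over the list alone (median -0.72, 1.55e-07; adjusted p = 0.519 with an estimated correlation). sagb (ENSDARG00000038378), an arrestin, was lower (-0.94 ± 0.15, adjusted p = 0.00125), whereas the photoreceptor transcription factor gene crx (ENSDARG00000011989) was higher (0.32 ± 0.07, adjusted p = 0.00137). On the liver list 19 of 32 genes were lower and 2 higher, or 21 and 2 adjusted over the list alone (median -0.71, 5e-08; adjusted p = 0.519 with an estimated correlation). fga (ENSDARG00000020741), a fibrinogen chain, stood at 16.4 ± 1.79 against 32.1 ± 5.84 CPM (-0.97 ± 0.13, adjusted p = 5.55e-05) and RBP2 (ENSDARG00000093774), a retinol-binding protein, at 4.27 ± 0.362 against 13.1 ± 3.83 CPM (-1.62 ± 0.17, adjusted p = 2.48e-06). The intestine list had 6 of 16 genes lower and 1 higher, 6 and 1 adjusted over the list alone (median -0.60, 0.00336; adjusted p = 0.519 with an estimated correlation), among them MTTP (ENSDARG00000008637), which loads lipoproteins, at -0.88 ± 0.18, adjusted p = 0.00207. The pancreas list had 7 of 12 lower and 8 adjusted over the list alone (median -1.01, 0.00797; adjusted p = 0.525 with an estimated correlation). Without wild-type DMSO replicate 2, in which these organ lists stood highest, the pancreas call was lost (adjusted p = 0.065), its lower members numbered 2, and those of the liver, intestine and photoreceptor lists 14, 4 and 3. The pancreas and photoreceptor medians were then -0.55 and -0.42.

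**Figure D4:**
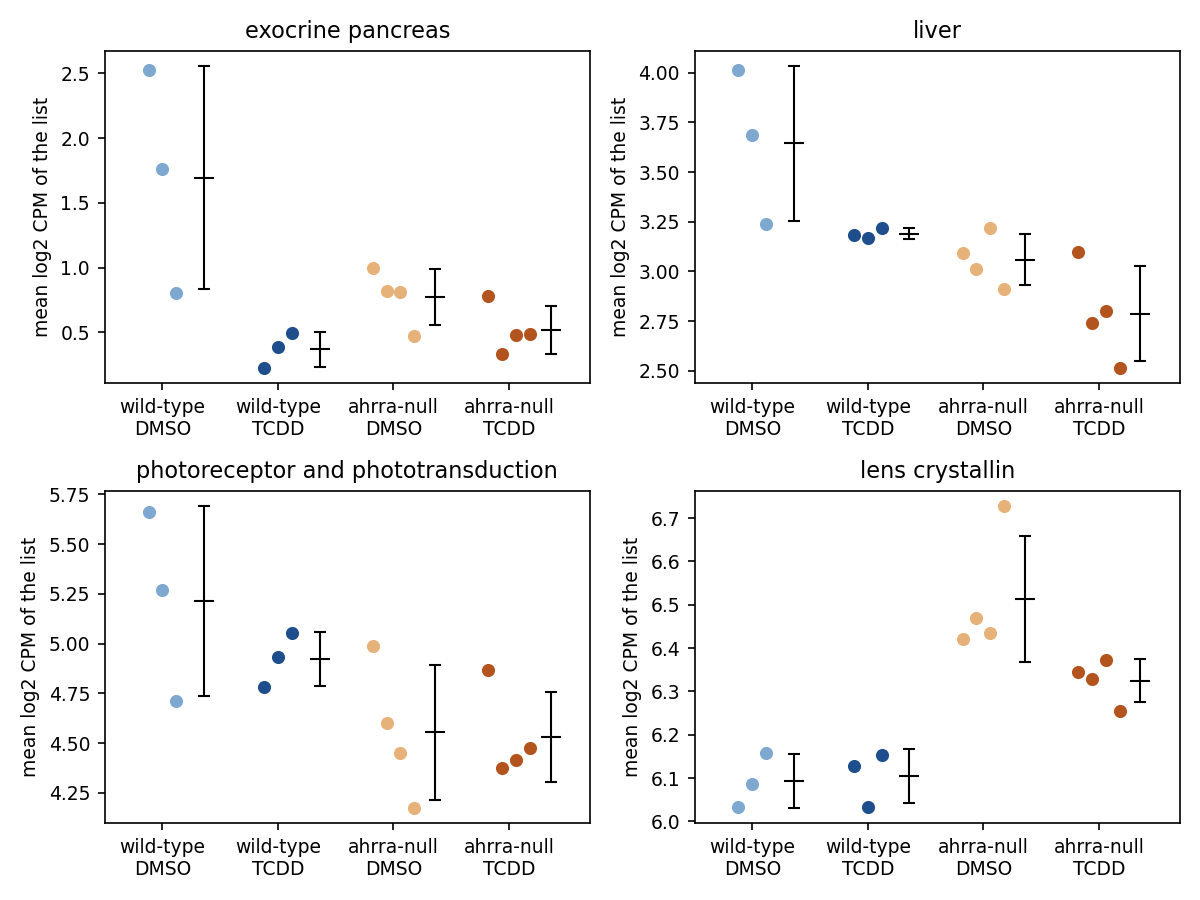
Mean log2 CPM of the exocrine pancreas, liver, photoreceptor and lens lists in each library, by group, with a point for each library and a black bar for the mean ± SD of the group. The wild-type DMSO libraries are spread from 0.80 to 2.52 on the pancreas list, and all 8 ahrra-null libraries lie above all 6 wild-type libraries on the lens list.

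Stress, clock and sterol genes also differed between the lines with carrier. On the Nrf2 list 10 of 22 genes were lower in ahrra-null and 0 higher, 10 adjusted over the list alone (camera adjusted p = 0.00388; adjusted p = 0.519 with an estimated correlation). They included the peroxiredoxin gene prdx1 (ENSDARG00000058734) at -0.48 ± 0.08, adjusted p = 0.000126 and glutathione reductase, GSR (ENSDARG00000019236), at -0.45 ± 0.08, adjusted p = 0.000394. gstp1.2, which is also on the AHR target list and is given below, was another of the lower genes. On the heat shock list 8 of 24 were lower and 2 higher, 10 and 3 adjusted over the list alone (0.00797; adjusted p = 0.519 with an estimated correlation). The mitochondrial chaperone gene HSPD1 (ENSDARG00000056160) stood at 121 ± 8.62 against 188 ± 25 CPM (-0.64 ± 0.07, adjusted p = 5.16e-07). On the clock list 11 of 35 were higher and 6 lower, 12 and 7 adjusted over the list alone (0.0199; adjusted p = 0.525 with an estimated correlation). ciarta (ENSDARG00000058094), a clock-associated repressor, stood at 109 ± 3.62 against 57.8 ± 1.2 CPM (0.92 ± 0.06, adjusted p = 2.05e-10), the period gene PER1 (ENSDARG00000012499) at 137 ± 8.45 against 71.2 ± 5.47 CPM (0.94 ± 0.06, adjusted p = 2.92e-10), and the cryptochrome gene cry3b (ENSDARG00000091131) at 28.1 ± 0.586 against 53.3 ± 5.25 CPM (-0.92 ± 0.08, adjusted p = 1.11e-08). The clock list's call was lost without wild-type DMSO replicate 4 (adjusted p = 0.178) or ahrra-null DMSO replicate 9 (0.0756). On the sterol list 9 of 24 were lower and 1 higher, 12 and 1 adjusted over the list alone (0.0107; adjusted p = 0.519 with an estimated correlation, and 0.0626 without wild-type DMSO replicate 2). srebf2 (ENSDARG00000063438), the regulator of sterol synthesis, was lower (-0.30 ± 0.05, adjusted p = 0.000434) and cyp11c1 (ENSDARG00000042014), a steroid hydroxylase, higher (0.76 ± 0.12, adjusted p = 8.6e-05).

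AHR targets were not called as a group with carrier (camera adjusted p = 0.326; 2 higher and 4 lower of 21, the same numbers adjusted over the list alone). CYP1A1 was 4.06 ± 0.634 against 6.74 ± 1.25 CPM (-0.73 ± 0.46, adjusted p = 0.298). Lower in ahrra-null were gstp1.2 (ENSDARG00000104068), a glutathione transferase, at -0.51 ± 0.09, adjusted p = 0.000975, and UGT1A1 (ENSDARG00000006220), a glucuronosyltransferase, at -1.22 ± 0.27, adjusted p = 0.00732, while the transporter gene SLC16A9 (ENSDARG00000104687) was higher (0.86 ± 0.12, adjusted p = 0.000125). The list named slc16a9a, and both genes printed as SLC16A9 were taken for it. The other gene (ENSDARG00000013926) measured 5.38 to 5.67 CPM in wild-type DMSO and 4.67 to 6.53 CPM in ahrra-null DMSO. Which of them is slc16a9a was not settled. The other 15 lists were not called. The count of differing genes was 2844 without wild-type DMSO replicate 2 and 3038 with 1 surrogate variable, and 663 genes differed at least 2-fold. The surrogate variable itself partly followed the genotype.

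With TCDD the lines differed in 5577 genes (25.8%), 2754 higher and 2823 lower in ahrra-null, and 585 at least 2-fold. FBN2 stood at 10.4 ± 1.05 against 0.954 ± 0.51 CPM (3.39 ± 0.29, adjusted p = 1.27e-06), RXFP2 (ENSDARG00000032820) at 14.5 ± 0.875 against 2.36 ± 0.168 CPM (2.62 ± 0.20, adjusted p = 1.23e-07), ms4a17a.9 at 1.54 ± 0.475 against 10.5 ± 2.83 CPM (-2.76 ± 0.25, adjusted p = 1.13e-06) and PIPOX at 1.08 ± 0.146 against 6.15 ± 0.449 CPM (-2.51 ± 0.17, adjusted p = 4.19e-10). The activity-regulated transcription factor gene NPAS4 (ENSDARG00000055752) stood at 46.7 ± 3.59 against 7.90 ± 2.86 CPM (2.59 ± 0.24, adjusted p = 2.35e-05) and the receptor gene gpr3 (ENSDARG00000094860) at 16.5 ± 1.74 against 4.37 ± 0.755 CPM (1.93 ± 0.13, adjusted p = 6.43e-10). DISP3 (ENSDARG00000036999) was lower (-1.61 ± 0.14, adjusted p = 5.88e-07), as was the glucose transporter gene SLC2A1 (ENSDARG00000001437) (-1.61 ± 0.31, adjusted p = 0.00232). The genotype differences with carrier and with TCDD, which share no library, had 3258 genes called in both, 1560 higher in both, 1696 lower in both and 2 in opposite directions, against 273 and 330 of independent lists. These lists also came from the same fit and are not fully independent. Across the 6989 genes called in either, Pearson r was 0.877 and Spearman rho 0.885, across genes, and 96.8% had the same sign. Over all tested genes Pearson r was 0.799.

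Among AHR genes with TCDD, ahrra was higher in ahrra-null, as given above, and ahrrb was lower (2.73 ± 0.89 against 4.91 ± 1.13 CPM, -0.85 ± 0.26, adjusted p = 0.0198). The ahrrb call was lost without wild-type TCDD replicate 6 (adjusted p = 0.114) or 8 (0.0624). CYP1A1 did not pass (-0.48 ± 0.27, adjusted p = 0.216), nor did cyp1c1 (0.19 ± 0.19, adjusted p = 0.5). As a group the targets were not called (camera adjusted p = 0.838; 3 higher and 4 lower of 21, the same numbers adjusted over the list alone). ahrra-null TCDD replicate 15, in which these genes stood low, is among the libraries compared. gstp1.2 (-0.46 ± 0.09, adjusted p = 0.00159), NQO1 (-0.30 ± 0.08, adjusted p = 0.00807) and UGT1A1 (-1.01 ± 0.25, adjusted p = 0.0116) were lower. SLC16A9 (ENSDARG00000104687, 0.90 ± 0.12, adjusted p = 4.13e-05) was higher. The other gene of that symbol (ENSDARG00000013926) measured 4.62 to 5.51 CPM in wild-type TCDD and 4.71 to 6.96 CPM in ahrra-null TCDD. On the Nrf2 list 10 of 22 were lower and 2 higher, 10 and 3 adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.633 with an estimated correlation). They included TXNRD3 (ENSDARG00000100374), a thioredoxin reductase, at -0.40 ± 0.05, adjusted p = 8.7e-06 and prdx1 at -0.55 ± 0.08, adjusted p = 1.43e-05. gstp1.2 and NQO1, given above among the AHR targets, are on this list too and count among its lower genes. On the heat shock list 9 of 24 were lower and 2 higher, 9 and 3 adjusted over the list alone (0.0161; adjusted p = 0.633 with an estimated correlation), with HSPD1 at -0.68 ± 0.07, adjusted p = 2.25e-07.

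Lens, muscle, clock and cell cycle lists differed with TCDD. Of 22 lens genes 7 were higher and 0 lower, 10 and 1 adjusted over the list alone (median 0.20, 0.00142; adjusted p = 0.633 with an estimated correlation), with CRYAA at 48.7 ± 3.24 against 23.4 ± 1.1 CPM (1.05 ± 0.10, adjusted p = 5.02e-07). The median was 0.13 without wild-type TCDD replicate 7. Of 25 fast muscle genes 10 were higher and 2 lower, the same numbers adjusted over the list alone (0.013; adjusted p = 0.681 with an estimated correlation, and 0.0771 without ahrra-null TCDD replicate 13). The skeletal actin gene ACTA1 (ENSDARG00000036371) stood at 609 ± 70.0 against 302 ± 26.5 CPM (1.01 ± 0.14, adjusted p = 0.000231). Of 26 cell cycle genes 13 were lower and 2 higher, 15 and 2 adjusted over the list alone (median -0.21, 0.00142; adjusted p = 0.633 with an estimated correlation), with RRM1 at -0.49 ± 0.07, adjusted p = 4.7e-05. On the p53 list 5 of 20 were higher and 2 lower, 8 and 2 adjusted over the list alone (0.0395; adjusted p = 0.633 with an estimated correlation), led by cdkn1a (ENSDARG00000076554), a cell cycle inhibitor, at 1.08 ± 0.16, adjusted p = 2.77e-05. That list's call was lost without wild-type TCDD replicate 6 (adjusted p = 0.0806) or ahrra-null TCDD replicate 13 (0.0771). The clock list had 14 of 35 higher and 4 lower, 17 and 4 adjusted over the list alone (0.0137; adjusted p = 0.633 with an estimated correlation), with ciarta at 0.89 ± 0.06, adjusted p = 2.6e-10 and cry3b at -1.05 ± 0.08, adjusted p = 1.69e-09.

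The liver list had 10 of 32 genes lower in ahrra-null with TCDD and 1 higher, 13 and 1 adjusted over the list alone (median -0.57, camera adjusted p = 0.00142; adjusted p = 0.681 with an estimated correlation), with fga at 14.6 ± 2.62 against 26.5 ± 1.44 CPM (-0.86 ± 0.13, adjusted p = 0.000154). The photoreceptor list had 3 higher and 3 lower of 39, 2 and 0 adjusted over the list alone (median -0.24, 0.0217; adjusted p = 0.755 with an estimated correlation). Its called members went both ways, with crx higher (0.37 ± 0.07, adjusted p = 0.000214). Its call was lost without wild-type TCDD replicate 8 (adjusted p = 0.0826) or ahrra-null TCDD replicate 14 (0.066). The sterol list had 7 of 24 lower and 1 higher, 8 and 2 adjusted over the list alone (0.0462; adjusted p = 0.633 with an estimated correlation), with srebf2 at -0.40 ± 0.05, adjusted p = 1.02e-05. Its call was lost without wild-type TCDD replicate 7 (adjusted p = 0.0597), ahrra-null DMSO replicate 10 (0.0565) or ahrra-null TCDD replicate 14 (0.0764), and with a filter of 1 CPM in 3 libraries (0.0566). The other 15 lists, exocrine pancreas (camera adjusted p = 0.552) and intestine (0.0601) among them, were not called.

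Whether the lines responded differently to TCDD was tested by the interaction of genotype and TCDD. No gene passed with edgeR's quasi-likelihood test: 0 of 21606, with 1117 at an unadjusted p under 0.05 where 1080.3 would be expected and a smallest adjusted p of 0.277. The number at an unadjusted p under 0.05 depended on the setting. It was 786 with DESeq2, 847 without wild-type DMSO replicate 3, 1918 with limma voom and 2255 without wild-type DMSO replicate 4. DESeq2 called 8 genes and limma voom 6. The AHR genes gave an interaction log2 fold change of 0.25 ± 0.53, adjusted p = 0.986 for CYP1A1, 0.56 ± 0.32, adjusted p = 0.963 for cyp1c1 and 1.00 ± 0.84, adjusted p = 0.973 for ahrra, positive where the rise was larger in ahrra-null. ahrra-null TCDD replicate 15 stood lowest of its group in each of these genes. Genes that DESeq2 or voom called, and that were therefore chosen after their values were seen, included the shear-responsive transcription factor gene klf2b (ENSDARG00000040432), with an edgeR interaction of 0.90 (adjusted p = 0.373), the histone gene histh1l1 (ENSDARG00000035519) at 0.49 (adjusted p = 0.277), the keratin gene cyt1 (ENSDARG00000092947) at 0.59 (adjusted p = 0.726) and NPAS4 (ENSDARG00000055752) at 1.64 (adjusted p = 0.695). edgeR called 10 genes without wild-type DMSO replicate 4, 2 (klf2b and cyp1c1) without ahrra-null TCDD replicate 15, 1 without ahrra-null DMSO replicate 12 and 1 (klf2b) without ahrra-null TCDD replicate 16.

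Gene lists gave an interaction where single genes did not, and none of these calls held with an estimated correlation. The heart list (median interaction 0.37, 3 members positive adjusted over the list alone, camera adjusted p = 1.75e-05; adjusted p = 0.212 with an estimated correlation) and the exocrine pancreas list (median 1.21, 3 adjusted over the list alone, 1.44e-06; adjusted p = 0.303 with an estimated correlation) had positive interactions, toward a smaller fall or a larger rise with TCDD in ahrra-null. The cell cycle list (median -0.22, 1 negative adjusted over the list alone, 3.92e-12; adjusted p = 0.212 with an estimated correlation) and the lens list (median -0.23, 8.91e-07; adjusted p = 0.303 with an estimated correlation) went the other way. The lens median was -0.14 without ahrra-null DMSO replicate 12, and the pancreas median 0.69 without wild-type DMSO replicate 2. The photoreceptor and liver lists, which like the pancreas list were spread widely among the wild-type DMSO libraries, had medians of 0.28 and 0.23 (2.84e-05 and 0.0105; adjusted p = 0.702 and 0.801 with an estimated correlation). Without wild-type DMSO replicate 2 both calls were lost (adjusted p = 0.278 and 0.901), and the liver call also without ahrra-null DMSO replicate 12 (0.0994) or TCDD replicate 13 (0.381). The photoreceptor and liver medians were 0.07 and 0.0078 without wild-type DMSO replicate 2, 0.52 and 0.43 without replicate 4, and 0.15 and 0.13 without ahrra-null TCDD replicate 13. The photoreceptor median was also 0.51 without ahrra-null DMSO replicate 9. The AHR targets were not called as a group (camera adjusted p = 0.164). Genes called in a single line mostly pointed the same way in the other line: the 58 called as falls in wild type alone (54 of the same sign) had medians of -0.67 in wild type and -0.21 in ahrra-null, and the 106 called as rises in ahrra-null alone (94 of the same sign) 0.48 in ahrra-null and 0.25 in wild type. These genes were picked for passing in a single line, so no difference between the lines is read from the medians.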

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

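The tests of all 3 patterns weighed here were chosen after the results were seen.

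The rise of AHR targets was weaker in ahrra-null TCDD replicate 15 than in the other libraries of its group: over the 11 that rose, it kept a median share of 0.405 of the rise in the mean of the other 3 (0.237 to 0.520). It held 16.9 M counts, no fewer than a library with the full rise, and 465 CPM of CYP1A1 against at most 4.78 CPM in the ahrra-null DMSO libraries, which argues against low depth and against an unexposed sample. RNA of unexposed embryos in the sample would shrink every change to that share, and 12 genes that rose 2-fold or more in wild type and lie off the AHR target list came near it, with a median log2 change of 0.83 where a mixture would give 0.885. Falls were shrunken less, which argues, though weakly, against a mixture as the whole cause: 78 genes called as falls in ahrra-null kept a median share of 0.72 (quartiles 0.518 and 0.981; 62 under 1), with replicate 15 among the libraries that chose them, and 69 that fell in wild type had a median of -0.268, where a mixture would give -0.093 and the other 3 libraries had -0.36 to -0.19, a distance of 2.91 pooled SD of single libraries (0.0601) but just under 2 SD of these 3 alone (0.0881). A lower effective exposure may give such a share and stays open, as does a mixture as part of the cause, and no biological explanation was tested, since the design gives none within a group.

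The pancreas, liver, intestine and photoreceptor lists were called lower in ahrra-null DMSO than in wild-type DMSO, where they were spread widely, but none was called with an estimated correlation (adjusted p 0.519 to 0.525) and 18 of 35 splits of the libraries called as many lists. Without wild-type DMSO replicate 2, in which they stood highest, 4 of 4 lists kept over 50% of their median difference (pancreas -0.55, liver -0.54, intestine -0.51, photoreceptor -0.42). The shares kept were 54.0%, 75.9%, 85.2% and 57.8% in that order. This argues against that library alone, but it carried a large part of the pancreas and photoreceptor differences. Members called lower went from 7, 19, 6 and 9 to 2, 14, 4 and 3 in the same order. A difference in developmental pace between samples is a candidate explanation, since the 4 list means rose and fell together within groups: Pearson r over 14 libraries, as deviations from group means, was 0.762 to 0.952 in the 6 relations (two-sided permutation p within groups 5e-05 to 0.0253, adjusted 3e-04 to 0.0253) and Spearman rho 0.644 to 0.982 (p 5e-05 to 0.0472, adjusted 3e-04 to 0.0472). Without the 2 libraries farthest from the median, wild-type DMSO replicates 2 and 4, r was 0.521 to 0.941. Such a correlation within groups does not show that pace makes the genotype difference, and an effect of the genotype itself stays open. Pace was weighed on the 4 lower lists alone. The lens list went the other way in ahrra-null DMSO (15 of 22 genes higher, 0 lower, median 0.46) and was not weighed.

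Many genes differed between genotypes with either exposure. Library size is argued against: ahrra-null libraries held more counts on average than wild type with DMSO (20.3 and 19.0 M) and fewer with TCDD (17.5 and 19.8 M, with 3 of 4 below every wild-type TCDD library), yet 96.8% of the genes called with either exposure differed in the same direction with both. Sampling at another time of day stays open: the bmal, clock and npas2 genes had a median of -0.0795 in DMSO (6 genes, 1 lower) and the per, cry, nr1d and ciart genes 0.30 (18 genes, 9 higher and 3 lower), and in TCDD -0.09 and 0.34. Separate parents, clutches or rearing of the lines may part them too, and cannot be told apart from the lesion, since the labels tie no clutch to both lines; the first principal component, with 42.1% of the variance, follows the genotype. The loss of ahrra, the difference the design names, is untested against these.

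Named genes were screened for an outlying library with Dixon's test in the ahrra-null groups of 4 libraries. The wild-type groups were not screened, so nothing is said here of outlying libraries in them. Wild-type DMSO replicates 2 and 4 differed most of all replicate pairs (chi-square per degree of freedom 18.4). In 16 of 206 groups tested, a library lay far from the others, where chance alone gives about 1 in 20 independent groups (10.3). Genes that move together in a library, as AHR targets did, are not independent, so 16 is not weighed against 10.3. Of the 16, 10 were in ahrra-null TCDD replicate 15. There fgf7 was 18.1 CPM (38.4 to 40.8 in the others), CYP1B1 17.2 (37.9 to 38.5), ugt1b5 39.5 (54.2 to 56.5), CYP1A1 465 (1057 to 1103), cyp1c1 216 (387 to 421), cyp1c2 39.9 (84.6 to 92.4) and cxcl12b 35.3 (25.4 to 26.4). ACTA1 (ENSDARG00000036371) was 505 (629.7 to 651), LFNG (ENSDARG00000037879) 124 (109 to 111) and dnajb1b (ENSDARG00000041394) 4.42 (4.70 to 4.72). In ahrra-null DMSO replicate 12, CRYAA was 62.7 (48.2 to 50.5), BFSP1 (ENSDARG00000074919) 13.2 (10 to 10.5) and TXNRD3 89.7 CPM (81.6 to 82.9). fga was 19.1 CPM in ahrra-null DMSO replicate 11 (15.1 to 15.8), TTR (ENSDARG00000037191) 1.04 in ahrra-null DMSO replicate 9 (0.503 to 0.578), and MFAP4 (ENSDARG00000088745) 0.833 in ahrra-null TCDD replicate 14 (1.34 to 1.42).

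The TCDD effect differed between genotypes for 12 lists by the interaction test with the preset correlation, and for 0 with an estimated correlation. The median interactions of the heart, exocrine pancreas, photoreceptor, liver, lens and cell cycle lists were 0.37, 1.21, 0.28, 0.23, -0.23 and -0.22. Those of the others were 0.83 for germ and maternal stock (camera adjusted p = 0.00277; adjusted p = 0.15 with an estimated correlation), 0.10 for epidermis (0.0122 and 0.745), 0.0931 for fast muscle (0.0063 and 0.745), 0.0873 for neuronal genes (0.00374 and 0.702), 0.0701 for vascular endothelium (0.0116 and 0.212) and -0.0846 for erythroid genes (0.00416 and 0.303). Without wild-type DMSO replicate 4 the erythroid (adjusted p = 0.0781) and vascular (0.0597) calls were lost. The neuronal call was lost without ahrra-null DMSO replicate 12 (0.171). The fast muscle call was lost without wild-type DMSO replicate 2 (0.304), ahrra-null DMSO replicates 9 (0.0828) or 10 (0.138) or ahrra-null TCDD replicate 13 (0.362). The epidermis call was lost without wild-type DMSO replicates 2 (0.267) or 3 (0.105), wild-type TCDD replicate 8 (0.063), ahrra-null DMSO replicates 10 (0.346) or 11 (0.0967), or ahrra-null TCDD replicates 13 (0.135) or 14 (0.0684). Some of these medians moved by more than 1.5 times when 1 library was left out. Without wild-type DMSO replicate 2 they were 0.04 for fast muscle, 0.03 for epidermis, 0.13 for vascular, 0.55 for germ, 0.69 for pancreas, 0.07 for photoreceptor and 0.0078 for liver genes. Without wild-type DMSO replicate 4 they were 0.14 for fast muscle, 0.52 for photoreceptor, -0.01 for erythroid, 0.43 for liver and 0.21 for epidermis. Without wild-type TCDD replicate 6 epidermis had 0.06, and without replicate 7 erythroid genes had 0.0062. Without ahrra-null DMSO replicate 9 fast muscle had 0.06, photoreceptor 0.51 and erythroid genes -0.06, and without replicate 11 epidermis had 0.06. Without ahrra-null DMSO replicate 12 lens had -0.14, erythroid -0.04, neuronal 0.04, epidermis 0.22 and vascular genes 0.11. Without ahrra-null TCDD replicate 13 fast muscle had 0.05, photoreceptor 0.15, erythroid -0.02 and liver genes 0.13. Without ahrra-null TCDD replicate 15 epidermis had 0.18, and without replicate 16 vascular genes had 0.11.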

How the results depend on the processing

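All alternatives were planned, and no result of a named gene changed direction where it was called, with the chosen settings or with the alternative. Some that were called with neither did, gstp1.1 (ENSDARG00000103019) and LFNG (ENSDARG00000037879) for TCDD in wild type among them. Results of named genes were counted once for each gene and each alternative. The 2-fold threshold is among these and ends every call of a smaller change. Called results kept their call in 1036 such cases and lost it in 112 for TCDD in wild type, and in 1014 and 136 for TCDD in ahrra-null. For genotype they kept it in 1318 and lost it in 62 in DMSO, and in 1483 and 58 in TCDD. Results not called were called in 19 cases for the interaction, 6 and 5 for genotype in DMSO and TCDD, and 5 and 8 for TCDD in wild type and ahrra-null. With a threshold of 2-fold the called genes numbered 53 and 44 for TCDD in wild type and ahrra-null, 663 and 585 for genotype in DMSO and TCDD, and 25 called in both TCDD comparisons, since it asks for more of the same genes. With 1 surrogate variable they numbered 381 (214 higher) and 394 (225 higher) for TCDD in wild type and ahrra-null, 166 in both, and 3038 (1510 higher) for genotype in DMSO. That variable partly followed the genotype, at -0.21 to 0.57 in wild-type DMSO and -0.31 to 0.06 in ahrra-null DMSO. The genotype count with it is therefore no neutral check. limma voom called 381 genes (159 higher and 222 lower) for TCDD in wild type and 6 in the interaction, with a Pearson r of 0.832 between the TCDD effects, and DESeq2 called 8 in the interaction. The cause of these differences was not tested. The other scalings moved the share of higher calls by less than 4 percentage points and left the median of all genes within 0.01 of 0. Camera with an estimated correlation called 2 lists for TCDD in wild type (AHR targets and heart muscle), 1 in ahrra-null (AHR targets) and 0 in each other contrast. Fry called 4 lists for TCDD in wild type, 4 in ahrra-null, 13 for genotype in DMSO, 11 for genotype in TCDD and 1 in the interaction, where camera with the preset correlation called 11, 11, 9, 10 and 12. The preset correlation takes list members to vary almost independently, so these calls rest on that assumption. Leaving out 1 library gave 82 to 388 genes for TCDD in wild type, 141 to 374 for TCDD in ahrra-null, 2844 to 5019 for genotype in DMSO, 3931 to 6090 for genotype in TCDD and 0 to 10 for the interaction. Called lists numbered 10 to 14, 9 to 15, 8 to 10, 9 to 13 and 9 to 13 in the same order. Genes called in both TCDD comparisons numbered 58 to 108 and Pearson r was 0.801 to 0.926. Each of these fits had 1 sample fewer, and the cause beyond that was not tested. Leaving out genes on the chromosome of ahrra was not run. No paired analysis was run, because the labels tie no library of a group to a library of another. The replicate numbers run on from group to group, so they neither show nor exclude pairs. No sample is numbered 1 or 5. At 16.9 to 23.1 M counts per library, genes near the filter, ahrra with carrier among them, have wide errors.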

Other observations

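Single genes, most of them outside the naming rule, were also called with TCDD in both lines. Those of this paragraph and the next were chosen after their values were seen, and no group of genes was tested through them. CXCR4 (ENSDARG00000057633), a chemokine receptor that guides migrating cells, rose by 1.05 in wild type (adjusted p = 0.00106) and 1.15 in ahrra-null (4.38e-05) on the log2 scale. The genes for its ligand fell: CXCL12 (ENSDARG00000037116) had log2 fold changes of -0.46 (0.000227) and -0.30 (0.00372), and cxcl12b -0.75 (0.0085) and -0.84 (0.000624). Further rises in both lines included the laminin gene LAMB1 (ENSDARG00000045524) by 0.77 (2.21e-05) and 0.79 (1.79e-06), the thrombospondin gene THBS3 (ENSDARG00000012060) by 0.86 (9.51e-07) and 0.67 (2.72e-06), the matricellular gene ccn2b (ENSDARG00000104292) by 0.88 (3.72e-05) and 1.19 (3.29e-08), and the forkhead gene foxf2a (ENSDARG00000017195) by 0.86 (2.21e-05) and 0.85 (1.87e-06). BMP4 (ENSDARG00000019995), a growth factor, rose by 0.48 (0.00428) and 0.42 (0.00351).

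mb (ENSDARG00000031952), myoglobin, fell in both lines, with log2 fold changes of -0.65 in wild type (adjusted p = 1.29e-06) and -0.33 in ahrra-null (0.00087). LRAT, which stores retinol as esters, had -1.06 (1.9e-05) and -0.83 (3.89e-05), and HSD11B2 (ENSDARG00000001975), which inactivates cortisol, -0.56 (0.000752) and -0.61 (2.81e-05). The interaction tests of these genes are among the 21606 of which 0 passed.

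The counts of called genes were set against other splits of the same libraries into groups of the same sizes, as planned. Brackets give the count of the real split and then the highest count of any other. For TCDD in ahrra-null only the real split of 35 gave as many genes (254 and 4). The same held for genotype, with 1 of 35 in DMSO (4670 and 1253) and 1 of 35 in TCDD (5577 and 1677). The smallest share this test can give is 1 of 35. The other splits mix the compared groups, which widens the spread within them, so chance is not excluded by these counts alone. For genes called in both TCDD comparisons 1 of 100 drawn splits gave as many (93; 1). For TCDD in wild type the 10 splits are too few for a share under 0.05; 1 of them gave as many genes (185; 1) and 3 as many lists (11; 14). In the interaction 100 of 100 drawn splits gave at least 0 genes (highest other 9), which tests nothing. Counts of called lists were reached by 5 of 35 splits for TCDD in ahrra-null (11; 15), 18 of 35 for genotype in DMSO (9; 13), 5 of 35 for genotype in TCDD (10; 13) and 14 of 100 for the interaction (12; 14), so chance is not excluded for the number of called lists in these contrasts.

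For some lists that were not called, the sign of the camera test differed from that of the median or mean log2 fold change. These were the lens, erythroid, neutrophil, interferon, glia and vascular lists for TCDD in wild type, intestine and epidermis for TCDD in ahrra-null, and glia and cell cycle for genotype in DMSO. They were AHR pathway, bone and neuronal genes for genotype in TCDD, and Nrf2, bone, neutrophil and heat shock for the interaction.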
